A study of Rattus norvegicus with 6 samples.

How the data were processed

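Circular RNAs (circRNAs) are closed RNA loops that form when a downstream splice site joins an upstream one, and reads across that back-splice junction are counted to measure them. The samples were spinal cords of Wistar rats aged 8 weeks. Per the labels, 3 libraries came from rats with the cord transected (SCI) and 3 from rats with a laminectomy, the opening of the vertebral arch, without cord injury (sham). The design text calls the transection complete, while the series title can be read as saying incomplete, and the time between surgery and collection is not given in the sources used here. The labels do not say in words that each library came from its own rat, so p-values measure the spread between these libraries. Per the labels' protocols, Trizol was used for RNA extraction and an Illumina TruSeq RNA kit for the libraries. Whether linear RNA was removed is not given in the sources used here.

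The table used holds 11061 circRNAs in 6 libraries. The authors deposited whole-number counts of junction reads per circRNA, per the file headers, and these counts were not normalised. The authors also deposited log2 CPM (reads scaled by the library total) of the same reads, made with edgeR per the file headers. All 66366 of these log2 values matched a recomputation with edgeR's TMM scaling over all circRNAs and a prior count of 0.25, within a tolerance of 1e-06. The submitters' processing notes name Bowtie 0.12.2 and the genome build mm8, which is a mouse build although the samples are rat. The build behind the table's coordinates and the circRNA caller are not given in the sources used here, and coordinates are printed as the table gives them, counted from 1. Every circRNA in the table has 2 or more reads in at least 1 library, so circRNAs seen once only are outside this table, and a library with more reads brings more circRNAs into it. Total sequenced and mapped reads per library are unknown here, so back-splice reads cannot be set against all reads.

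The table assigns each circRNA to a class and, for 10393 of them, to a host gene symbol. Of the 4501 host symbols, 3845 are current symbols in the RefSeq gene table for the rat assembly GRCr8, which was used for names and synonyms only. Host gene sums add the counts of all circRNAs of a host apart from the 112 antisense ones. Back-splice reads total 9805 to 21255 per library. With so few reads, 1 read was worth 100 to 222 CPM in the circRNA fit. Reads without molecular identifiers are not independent molecules, so Wilson and exact binomial intervals and floors cover counting error only. No pair of libraries agreed within sampling noise: chi-square per degree of freedom lay between 2.21 and 5.24 over the 15 pairs.

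The main test was edgeR's quasi-likelihood F test (edgeR 4.0.16 in R 4.3.3) on counts, with TMM scaling, filterByExpr at a minimum count of 5 and a minimum total of 15, group as the only term, and Benjamini-Hochberg adjusted p under 0.05. CPM values are over the reads of the circRNAs or hosts that passed the filter, and standard errors (SE) are the log2 fold change divided by the root of the F statistic. The same test was run on host gene sums. Gene lists were tested on host sums with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry (limma 3.58.1), for lists with 5 or more tested hosts. The 23 lists were fixed before the data were examined, as were the designs and the alternatives other than those named as added. The share of each circRNA within its host was tested with edgeR's diffSpliceDGE. Totals, detected circRNAs and class shares were compared with a two-sided exact permutation test (SciPy 1.17.1), for which 3 against 3 libraries cannot give p below 0.10. Libraries were thinned to the smallest total by exact hypergeometric expectation.

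The circRNAs named in the text follow a rule fixed before the data were examined. It takes up to 10 higher and 10 lower circRNAs past the threshold by size of change, with a mean count at or above the median and no overlap of groups. Where a direction has none, it takes the 5 with the smallest p. It adds the 5 most abundant circRNAs, the most-read circRNA of up to 8 much-studied hosts, up to 4 hosts per list described (3 are given, for lists with 3 or more tested hosts) and the 3 hosts with the smallest p for a changed share. An item that the rule took is not reported here and was not replaced. Any other name was chosen after its values were seen. For a group with 0 reads the fold is a lower bound against 3 reads over the group, and 95% intervals of shares and ratios are Wilson or exact binomial. Those of the squared deviation over the expectation are percentile bootstraps over circRNAs. They measure the spread between circRNAs within a library and treat circRNAs as independent.

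The scripts were tested on simulated counts drawn from the real means and library sizes. Of 200 changed circRNAs, 55 at 2-fold, 58 at 4-fold and 65 at 8-fold were among the 515 tested. Of these, 14.5%, 55.2% and 96.9% were called, with 2 false calls among 105. The counts were drawn with the same common dispersion for all circRNAs. For host genes (722 tested) the shares were 14.8%, 64.9% and 95.3%, with 2 false calls among 109. A list of hosts (neuronal and synaptic) moved by 1 on the log2 scale was recovered (camera adjusted p = 7.04e-15). No other list was called, but the much-studied hosts, which share members with the moved list, were left out of that count. In the test of shares, the most-read tested circRNA of 30 hosts was changed 8-fold in abundance, which changes its share by less. Of these hosts, 15 were recovered, with 0 others. Alternatives covered DESeq2 size factors, no TMM, a minimum count of 10, no filter, a replicate block, leaving out each library, DESeq2 1.42.0, limma-voom, a minimum fold, and limma-trend on the log2 CPM values with 3 prior counts. Alternatives added after the data were seen were sample weights, sham replicate 2 as the only control, antisense circRNAs in host sums, the share of all reads per gene list, the same without each list's most-read host, and circRNAs grouped by circBase identifier.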

Results

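Back-splice reads were counted in 3 spinal cord libraries after transection (SCI) and 3 after laminectomy alone (sham), to ask which circRNAs differ after cord injury. The SCI libraries held 21255, 20847 and 19603 back-splice reads, and the sham libraries 11631, 9805 and 12722. Of the 11061 circRNAs, 6967 were exonic, 2845 overlapped their host in sense, 647 were intergenic, 490 intronic and 112 antisense. They came from 4443 host genes in sense, with the most from LOC102557203 with 25 circRNAs, the transcriptional corepressor gene Rere with 23 and the presynaptic scaffold gene Rims2 with 22. Across the circRNAs tested, the log2 CPM of SCI libraries correlated at 0.745 to 0.773 (Pearson, across circRNAs, which are not independent replicates), that of sham libraries at 0.370 to 0.522, and that of an SCI and a sham library at 0.498 to 0.633.

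More back-splice reads and more circRNAs were counted in the SCI libraries. SCI libraries had a mean of 20568 ± 861 reads (SD, n = 3) against 11386 ± 1474 (SD, n = 3) in sham, a ratio of 1.81. They held 4656, 4566 and 4488 circRNAs with at least 1 read, against 2556, 2775 and 2131. After thinning to 9805 reads the means were 3513 ± 21.4 and 2447 ± 351 circRNAs (SD, n = 3 each), a count that favours the larger libraries by construction, because the table holds only circRNAs with 2 or more reads in some library. None of the groups overlapped in these 3 measures, and each gave p = 0.10 in a two-sided exact permutation test, the smallest that n = 3 per group allows (0.20 after Benjamini-Hochberg adjustment over 10 measures). The 10 most abundant circRNAs took 8.97% ± 0.172 of reads in SCI and 8.99% ± 1.07 in sham (SD, n = 3 each; exact permutation p = 1). At equal totals of back-splice reads the order turned when more reads were asked for: the thinned means were 1802 and 1963 circRNAs with 2 or more reads, and 376 and 534 with 5 or more, higher in sham. The groups overlapped at 2 reads (exact permutation p = 0.2). At 5 reads they did not (exact permutation p = 0.10, and 0.20 adjusted over the 10 measures), and the difference of -158 was -79.6 without sham replicate 3. Total sequencing depth is unknown, so the totals do not show a change in circRNA per cell or per RNA.

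**Figure D1:**
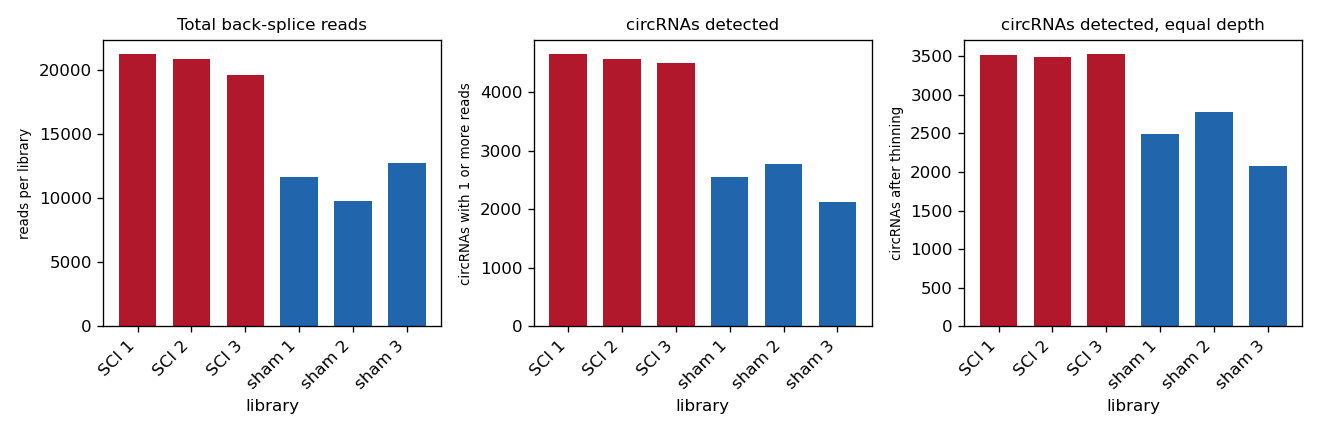
Bars give, for each of the 6 libraries, the total of back-splice reads (left), the circRNAs with 1 or more reads (middle) and the circRNAs expected after thinning every library to 9805 reads (right; this count favours the larger libraries), all on axes from 0. The SCI bars lie above the sham bars in each panel, from 19603 to 21255 reads against 9805 to 12722.

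Among single circRNAs, the junction within Lbr, which encodes the lamin B receptor of the inner nuclear membrane, was lower in SCI than in sham libraries. This circRNA (chromosome 13, 106627698 to 106634845, minus strand, sense overlapping, without a circBase identifier) had 25, 19 and 18 reads in SCI libraries and 59, 30 and 74 in sham. Its level was 2187 ± 279 CPM in SCI and 10555 ± 3406 in sham (SD, n = 3 each), a log2 fold change of -2.27 (SE 0.34, adjusted p = 0.00291 by edgeR's quasi-likelihood test). It was lower in all 3 SCI libraries than in any sham library. Its highest counts, 59 and 74, were in sham replicates 1 and 3. These libraries also had the highest squared deviation over the expectation, 5.38 and 6.76 at 8 to 20 expected reads. That expectation came from the SCI libraries, so differences between groups, that of Lbr included, raise these values. The values are thus not independent of the Lbr call, and whether uneven counts bear on it was not tested. Of the 484 circRNAs tested, 1 was lower and 0 were higher by edgeR at adjusted p under 0.05, while 30 had an unadjusted p under 0.05. DESeq2 and limma-voom each called 2, both lower: the Lbr circRNA and one assigned to Tuba1a.

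No circRNA passed the test in the higher direction, and the 5 with the smallest p are given as values. The circRNA of Myo19, a mitochondrial myosin gene (chromosome 10, 72109950 to 72119215, plus strand, exonic), had 14, 9 and 13 reads in SCI and 0 in each sham library, at least 6.64-fold higher against a floor of 3 reads over the sham group (adjusted p = 0.326 by edgeR). The circRNA of Hibadh, an enzyme gene of valine breakdown (chromosome 4, 147348731 to 147358990, minus strand, exonic), had 21, 20 and 15 reads against 0, 2 and 0. Relative to library totals that was a ratio of 15.5 (exact 95% interval 4.10 to 131; adjusted p = 0.326 by edgeR). An Ndrg3 circRNA (chromosome 3, 158659372 to 158715668, plus strand, sense overlapping) had 129, 97 and 84 reads against 30, 30 and 19, with a log2 fold change of 1.03 (SE 0.31, adjusted p = 0.393 by edgeR). The exonic circRNA of Robo1, an axon guidance receptor for Slit proteins (chromosome 11, 13687052 to 13689365, plus strand), had 33, 17 and 33 reads against 0, 4 and 6, a log2 fold change of 2.14 (SE 0.75, adjusted p = 0.719 by edgeR). The circRNA of LOC102554677 (chromosome 15, 51711939 to 51712461, plus strand) had 17, 19 and 17 reads against 2, 3 and 2.

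The most abundant circRNA was intergenic (chromosome X, 144352333 to 144354594, plus strand, with a circBase identifier). It had 75256 ± 7047 CPM in SCI and 66889 ± 11476 in sham (SD, n = 3 each), and its log2 fold change of 0.17 (SE 0.17) did not pass the test. Next came circRNAs of Nckap1, a member of the WAVE actin-regulatory complex (chromosome 3, 74283251 to 74316305, minus strand; log2 fold change -0.09, SE 0.21), and RGD1562952 (chromosome 2, 53079035 to 53084070, minus strand; -0.05, SE 0.25). The circRNA assigned to Tuba1a, an alpha-tubulin gene (chromosome X, 115123964 to 115145697, minus strand, sense overlapping), had 111, 107 and 99 reads in SCI and 121, 115 and 102 in sham, a log2 fold change of -1.01 (SE 0.22, adjusted p = 0.0760 by edgeR). The RefSeq table places Tuba1a on another chromosome, and tubulin genes have near-identical copies, so its host is uncertain. The same mismatch holds for Ddn, the host given to a circRNA nearby (chromosome X, 114925302 to 114927710). The build behind the coordinates is unknown, so the mismatch alone does not point to a tubulin copy. The circRNA of RGD1310862 (chromosome 10, 16616082 to 16622160, minus strand, exonic) stood at 0.52 (SE 0.24, adjusted p = 0.727 by edgeR).

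Much-studied circRNAs did not pass the test either. The most-read circRNAs of Nfix, Phf21a and Hipk3 had log2 fold changes of -0.08 (SE 0.26), -0.30 (SE 0.28) and -0.08 (SE 0.32). Those of Slc8a1, Fat3 and Dym stood at 0.15 (SE 0.55), 0.56 (SE 0.41) and 0.80 (SE 0.49), and that of Zfp609 at -0.06 (SE 0.62). The lowest adjusted p among these 7 was 0.920 (edgeR). Without the filter, the median log2 fold change of the 484 tested moved by 0.58, and the negative values of Nfix, Phf21a, Hipk3 and Zfp609 turned positive. The call for Lbr ended without sham replicate 1, with no filter and with limma-trend on log2 CPM, where 0 circRNAs passed, although its log2 fold change lay between -2.37 and -1.54 in all 19 alternatives, and without sham replicate 3 the count was 3 (1 higher, 2 lower). With sham replicate 2 as the only control, chosen after the data were seen, Lbr was not called, but that fit has no sham spread and assumes that this library varies like the SCI libraries.

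**Figure D2:**
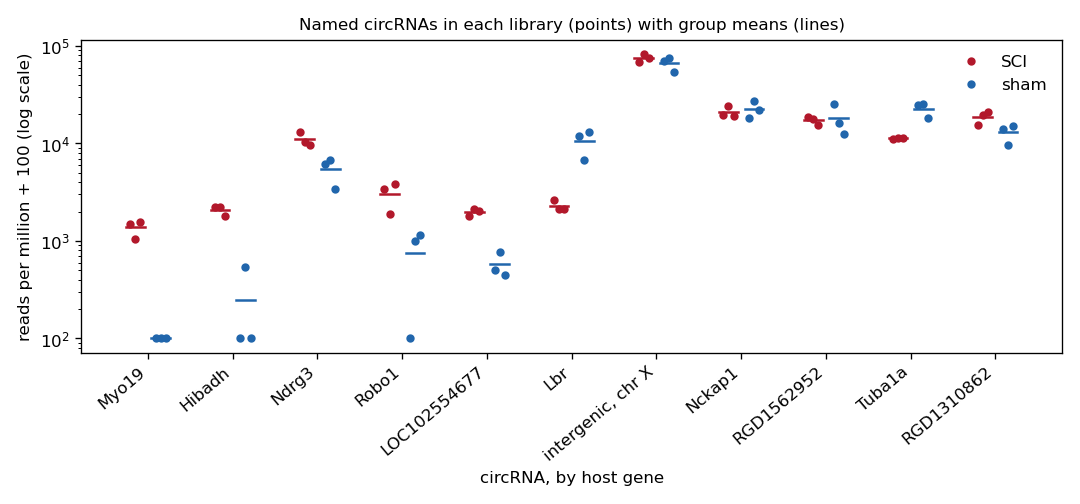
Points give CPM plus 100, on a log axis, of 11 named circRNAs in each SCI and sham library, and lines give the group means. The Lbr circRNA lies at 2187 CPM on average in SCI and 10555 in sham, and the Myo19 circRNA has 0 reads in the sham libraries.

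When circRNAs were summed by host gene, Lbr was lower and Myo19 higher in SCI than in sham libraries. Lbr, with a single circRNA, had a log2 fold change of -2.18 (SE 0.32, adjusted p = 0.00567 by edgeR). The 4 circRNAs of Myo19 had 65 reads in the 3 SCI libraries and 0 in sham, at least 12-fold higher against a floor of 3 reads over the sham group (adjusted p = 0.0480 by edgeR). Those were the 2 calls among 647 host genes, of which 42 had an unadjusted p under 0.05. Hosts chosen after their values were seen came next: the chromatin gene Ubn2 had 8526 ± 1059 CPM in SCI and 3898 ± 376 in sham (SD, n = 3 each; adjusted p = 0.102 by edgeR), and Tuba1a had 8424 ± 101 and 16189 ± 3073 (adjusted p = 0.102). The Myo19 call rested on a narrow margin: it ended with DESeq2 size factors, without TMM, with the replicate block, with limma-voom and with antisense circRNAs added. Over 20 alternatives it passed in 6, with adjusted p from 9.19e-04 to 0.838. Without SCI replicate 3 or sham replicate 1 no host passed, without SCI replicate 1 or sham replicate 2 there was 1, and without sham replicate 3 there were 8 (5 higher, 3 lower).

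Host genes of neuronal and synaptic function did not pass the test as a group. Of 24 tested members, 16 had a positive log2 fold change, 0 passed over all hosts and 0 adjusted over the list alone. Sv2c, a synaptic vesicle protein gene, had 33 reads in SCI and 1 in sham (ratio to totals 18.3, exact 95% interval 3.06 to 743), the synaptic scaffold gene Magi2 stood at 1.41 (SE 0.58) and Rapgef4, a cAMP-activated exchange factor gene, at -1.49 (SE 0.97). Camera gave an adjusted p of 0.975 for this list and fry 0.297. Without the filter 33 of 42 members were positive and fry, which does not compare a list with other hosts, gave an adjusted p of 0.00912 (0.00912 to 0.987 over the alternatives), while camera gave 0.199 and the median of the 647 hosts moved by 0.34. In axon guidance, 3 hosts were tested: Robo1 (2.38, SE 0.71), Dpysl2 (-1.97, SE 1.01) and Epha5 (0.27, SE 0.70). Robo1 was the 1 call adjusted over the list alone, against 0 over all hosts. Among voltage-gated ion channels (6 tested), the calcium channel gene Cacna1a stood at -0.88 (SE 0.71), and the potassium channel genes Kcnma1 and Kcnh1 at 0.30 (SE 0.87) and -0.29 (SE 1.02). Of 7 axonal cytoskeleton hosts, the spectrin gene Sptan1 stood at 2.08 (SE 1.22), Macf1 at -1.24 (SE 0.86) and Nav3 at 0.30 (SE 0.50). Of 3 glutamate receptor hosts, Grm5 stood at -1.16 (SE 0.87), Grik4 at 1.20 (SE 0.99) and Grik2 at -0.84 (SE 0.79).

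The tested oligodendrocyte and astrocyte hosts gave no call, and the oligodendrocyte precursor and microglia and macrophage lists had 0 tested hosts. Of 7 oligodendrocyte and myelin hosts, Plcl1 stood at 1.28 (SE 0.85), Rnf220 at -1.01 (SE 0.80) and Mbp, the myelin basic protein gene, at 0.43 (SE 0.38). Of 4 astrocyte hosts, Prex2 stood at -1.11 (SE 0.51), Slc4a4, a bicarbonate transporter gene, at 1.59 (SE 1.25) and Acsl6 at 0.21 (SE 0.55). Of 15 chromatin and ubiquitin hosts, Mycbp2 stood at -1.91 (SE 0.68) and Rere at 0.43 (SE 0.26). Of 23 much-studied hosts, 12 were positive, among them Dym (0.84, SE 0.34) and Mapk4 (1.02, SE 0.58). Of 4 autophagy and apoptosis hosts, Uvrag stood at 0.64 (SE 0.35), Vps13c at -1.37 (SE 0.85) and Wdfy3 at 0.86 (SE 1.17). Of the 6 lists with 5 or more tested hosts, 0 passed camera at the preset correlation (lowest adjusted p 0.975; lowest unadjusted p 0.272), 0 passed with an estimated correlation (lowest adjusted p = 0.975) and 0 passed fry. Fry also called much-studied hosts without the filter (adjusted p = 0.00388) and on circRNA-level values (0.0180), and voltage-gated ion channels without sham replicate 3 (0.00294). Camera with an estimated correlation gave adjusted p = 0.544, 0.878 and 0.832 for these, and 0.544 for neuronal and synaptic hosts without the filter. For 3 of them camera, which compares a list with all other hosts, pointed down while the median was positive: axonal cytoskeleton (median 0.30), chromatin and ubiquitin (0.05, mean -0.15) and much-studied hosts (0.10).

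As a share of all back-splice reads, hosts of 5 lists were lower in every SCI library than in any sham library, and no list was higher in this way, but 4 of these 5 gaps ended when the list's most-read host was left out. Oligodendrocyte precursor hosts kept theirs (0.0340% and 0.0888%), from few reads: 33 in SCI and 34 in sham with all hosts counted. A gap was then seen in 2 other lists, fibroblast and extracellular matrix hosts (0.0102% and 0.0747%) and chromatin and ubiquitin hosts (1.42% and 1.58%). Astrocyte hosts took 0.360% ± 0.0397 in SCI and 0.474% ± 0.0165 in sham, and endothelial and pericyte hosts 0.0741% ± 0.0214 and 0.164% ± 0.00909 (SD, n = 3 each). Without Prex2, astrocyte hosts took 0.285% ± 0.0162 and 0.306% ± 0.0535 (SD, n = 3 each), with overlap, and 3 of the 4 astrocyte hosts tested had a positive log2 fold change. Without Flt1, a VEGF receptor gene, endothelial and pericyte hosts took 0.0546% and 0.111%, also with overlap. The endothelial and neutrophil lists share the host Ebf1, so these gaps are not independent. Without Ebf1, which had 14 reads in SCI and 11 in sham, neutrophil and lymphocyte hosts took 0.00811% and 0.0346%, with overlap. Oligodendrocyte precursor hosts took 0.0534% and 0.0993%, GABA and glycine signalling hosts 0.241% and 0.336%, and neutrophil and lymphocyte hosts 0.0307% and 0.0675%. Each gave an exact permutation p of 0.10 and 0.46 after adjustment over the 23 lists, and chance gives such a gap in 10% of lists. Microglia and macrophage hosts took 0.0470% and 0.0973% with overlap, neuronal and synaptic hosts 3.16% and 2.81%, and oligodendrocyte and myelin hosts 0.751% and 0.740%. Some lists had few reads: skeletal muscle hosts had 12 reads in SCI and 0 in sham, red blood cell hosts 7 and 0, Schwann cell and peripheral nerve hosts 11 and 9, fibroblast and extracellular matrix hosts 13 and 26, ependymal and motile cilium hosts 25 and 6, and neutrophil and lymphocyte hosts 19 and 24. Without sham replicate 3 the difference was -0.0154 percentage points for neutrophil and lymphocyte hosts (-0.0367 with it) and -0.0164 for microglia and macrophage hosts (-0.0503 with it). Without SCI replicate 2 it was -0.0557 for GABA and glycine signalling hosts (-0.0948 with it). For neuronal and synaptic hosts it was 0.139 without sham replicate 2 (0.354 with it), and for axon guidance 0.0391 without SCI replicate 3 (0.0963 with it). The remaining lists overlapped between groups, with means of 0.0532% and 0.0833% for cell cycle and mitosis, 0.103% and 0.0965% for circular RNA biogenesis factors, 0.251% and 0.214% for inflammatory signalling, and 0.419% and 0.372% for autophagy and apoptosis. They were 0.283% and 0.327% for glutamate receptors, 0.505% and 0.633% for voltage-gated ion channels, 0.545% and 0.685% for axonal cytoskeleton, 0.539% and 0.442% for axon guidance, 2.14% and 2.13% for chromatin and ubiquitin, and 3.35% and 3.34% for much-studied hosts. Of the 23 differences, 10 turned with a library left out: without sham replicate 3 the sham means were 0.467% for voltage-gated ion channels and 0.478% for axonal cytoskeleton, below those in SCI. This comparison was chosen after the data were seen.

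**Figure D3:**
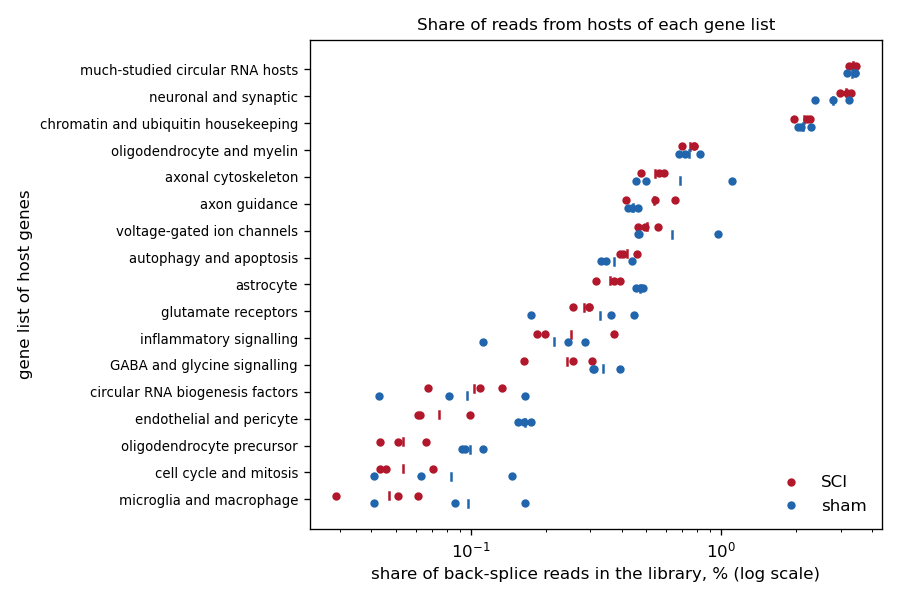
Points give the share of a library's back-splice reads, in % on a log axis, that came from hosts of each of 17 gene lists with at least 50 reads, for SCI and sham libraries, and lines give group means. Astrocyte and endothelial hosts lie at 0.360% and 0.0741% on average in SCI against 0.474% and 0.164% in sham.

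Within host genes, no circRNA passed the test for a changed share. The smallest p values were in RGD1560248, Tlk1, a chromatin-linked kinase gene, and Ralgapa1, a RalGAP subunit gene. The RGD1560248 circRNA (chromosome 3, 43657159 to 43692406) had 18, 12 and 13 reads in SCI and 3, 1 and 0 in sham, and its share moved by 2.48 on the log2 scale. The Tlk1 circRNA (chromosome 3, 63844435 to 63870473) had 6, 1 and 1 reads against 6, 4 and 11 (-1.92), and that of Ralgapa1 (chromosome 6, 86020613 to 86024909) had 42, 35 and 25 against 7, 9 and 11 (1.08). All 3 had an adjusted p of 0.983 (edgeR's diffSpliceDGE). Of 173 circRNAs in 69 hosts, 0 passed and 2 had an unadjusted p under 0.05.

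By class, exonic circRNAs took a higher share of reads in each SCI library than in any sham library, and intronic and sense overlapping ones a lower share. Exonic circRNAs held 63.1% ± 1.05 of reads in SCI and 60.3% ± 0.741 in sham, intronic ones 2.10% ± 0.172 and 3.16% ± 0.50, and sense overlapping ones 27.1% ± 0.838 and 28.5% ± 0.0547 (SD, n = 3 each). Each of these gave an exact permutation p of 0.10, the smallest possible with n = 3 (0.15 adjusted over 6 shares). Counted over detected circRNAs, exonic ones made up 68.2% and 66.3% (exact permutation p = 0.3) and sense overlapping ones 23.8% and 24.3% (p = 0.7 by the same exact test), with overlap, and intronic ones 2.86% and 3.76% without overlap. Without sham replicate 3 these differences were 0.416, 0.217 and -0.503 percentage points, against 1.87, -0.502 and -0.899 with it. Intergenic circRNAs took 7.28% and 7.38%, and antisense ones 0.470% and 0.594%, with overlap. CircRNAs with a circBase identifier, a grouping chosen after the data were seen, took 67.4%, 67.3% and 66.4% of reads in SCI and 61.0%, 62.7% and 59.7% in sham. Counted over detected circRNAs, the mean shares with an identifier were 55.8% and 56.3%, with overlap between groups (exact permutation p = 0.8) and a difference of 1.39 percentage points without sham replicate 2 and -2.06 without sham replicate 3. Among the 81 circRNAs with a mean of 20 or more reads, the 57 with an identifier had a median of 2.18 times as many reads in SCI as in sham, and the 24 without, Lbr and Tuba1a among them, 1.65 times. Of those 24, 23 were not exonic, so identifier and class overlap here, and this difference was not tested across libraries.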

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

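Among these alternatives, sample weights, sham replicate 2 as the only control, antisense circRNAs in host sums, the share of reads per gene list, with and without its most-read host, and the identifier grouping were chosen after the data were seen. The main count of 1 circRNA became 2 with a minimum count of 10, DESeq2, limma-voom and sample weights, 0 with no filter and with limma-trend at each of 3 prior counts, 3 (2 higher) with sham replicate 2 as the only control, and 0 to 3 with each library left out. The main count of 2 host genes became 1 with DESeq2 size factors, with no TMM and with antisense circRNAs added, 7 (6 higher) with no filter, 4 with DESeq2, 0 with sham replicate 2 as the only control, and 0 to 8 with each library left out. With 1 sham library the spread comes from the SCI libraries alone, so those counts say nothing about stability. Fewer libraries also enter the fits with a library left out, so a call lost there can come from the lower number alone. The highest counts of those fits, 3 circRNAs and 8 host genes, came without sham replicate 3. For the moved counts the cause was not tested. With the replicate number as a block, the counts were 2 circRNAs and 1 host gene, 0 lists and 0 shares; the numbers were not taken to pair the samples, since same-numbered libraries correlated at only 0.114, 0.0850 and 0.0804 in their deviations from the group means, although every sample correlated best with its own number, a hint from the data and not from the design. The Lbr circRNA was lower in all 19 alternatives and passed in 13 (adjusted p from 1.20e-08 to 0.457). Camera called 0 gene lists and diffSpliceDGE 0 circRNA shares in every alternative in which they were run, and the share of reads per list could not have passed with 3 against 3 libraries. Fry called 2 lists with no filter, neuronal and synaptic hosts (adjusted p = 0.00912) and much-studied hosts (0.00388), voltage-gated ion channels without sham replicate 3 (0.00294), and much-studied hosts on circRNA-level values (0.0180). Of 51 named values, 38 kept their sign in every alternative that tested them, and the 13 that did not were uncalled throughout. With no filter Nckap1 took 0.47, RGD1562952 0.53, Nfix 0.52, Phf21a 0.29, Hipk3 0.52 and Zfp609 0.56, and the host Kcnh1 0.10. With limma-trend at prior counts of 0.25, 0.125 and 0.5, Nckap1 took 0.51, 0.51 and 0.50, RGD1562952 0.59 in each, Nfix 0.50 in each, Phf21a 0.30, 0.30 and 0.29, Hipk3 0.50 in each, Zfp609 0.85, 0.86 and 0.82, and Kcnh1 1.19, 1.5 and 0.89. The median log2 fold change of the tested circRNAs moved by 0.58 with no filter, by 0.91, 0.96 and 0.82 with limma-trend, and by 0.21 with limma-voom; these settings differ in more than scaling, and the cause was not tested. Without TMM RGD1562952 took 0.0029 and Zfp609 0.0027; with the block Zfp609 took 0.12 and Kcnh1 0.031; with limma-voom RGD1562952 took 0.018, Zfp609 0.17 and Kcnh1 0.43, and with sample weights Zfp609 took 0.21 and Kcnh1 0.51. With sham replicate 2 as the only control, RGD1562952 took 0.17, Nfix 0.16, Hipk3 0.20, Slc8a1 -0.53, Zfp609 1.63, Grik2 0.93 and Cacna1a 0.99; the cause was not tested. Leaving out each library gave -0.16 to 0.18 for Nckap1, -0.12 to 0.42 for RGD1562952, -0.19 to 0.13 for Nfix, -0.25 to 0.30 for Hipk3, -0.23 to 0.85 for Slc8a1, -0.34 to 0.95 for Zfp609, and for hosts -0.38 to 0.83 for Kcnma1, -0.76 to 0.79 for Kcnh1, -0.28 to 0.57 for Acsl6 and -0.23 to 1.15 for Epha5. SCI minus sham in circRNAs detected at equal totals of back-splice reads turned from 1066 to -161 with 2 reads asked for and -158 with 5. The difference in the share of the 10 most abundant circRNAs ran from -0.501 to 0.563 percentage points with each library left out, that of antisense circRNAs from -0.191 to 0.00368 and that of intergenic ones from -0.331 to 0.214. The difference for circRNAs with an identifier turned from 5.92 to -0.434, with overlapping groups, when detected circRNAs were counted, and was then 1.39 without sham replicate 2; the cause was not tested. The median circRNA tested had a mean of 8.67 reads. In simulated counts with these means and library sizes, 14.5% of 2-fold, 55.2% of 4-fold and 96.9% of 8-fold changes were called. That simulation held 200 changed circRNAs at a common dispersion and gave 105 calls, against 1 in the real data. More calls ease the adjusted threshold, so these shares may be too high for the real data. Even there, 2-fold changes were mostly not called. Depth and spread between libraries were not separated.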

Other observations

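Of the tests in this part, those of thinning and of pooled draws were set out before their results were seen, and all others after. Some circRNAs were seen in all libraries of one group and in none of the other. After Myo19, those with the most reads in SCI libraries alone were from Hecw1, a ubiquitin ligase gene (13, 10 and 3 reads), Chd9, a chromatin remodeller gene (3, 15 and 8), and Magi3, a scaffold gene (6, 5 and 15). Those seen in sham alone included circRNAs of Mtrf1, a mitochondrial translation release factor gene (7, 3 and 7 reads), Arap2 (4, 3 and 8), Coq3, an enzyme gene of ubiquinone synthesis (4, 2 and 6), and Ptprd, a receptor phosphatase gene (3, 1 and 7). These names were chosen after their values were seen, and none of these circRNAs had enough reads to enter the edgeR test with its filter.

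The real split of the 6 libraries gave 1 circRNA and 2 host genes, against at most 0 of each in the other 9 splits, and 1 of the 10 splits gave as many in each case. For gene lists (camera) and circRNA shares the real split gave 0, which all 10 splits reached, and the highest other was 1 for each. With 10 splits no share under 0.05 can be reached.

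The surplus of circRNAs found in SCI alone was set against library size. There were 318 circRNAs in all 3 SCI libraries and no sham library, and 7 the other way round. In 100 draws of all 6 libraries from one common pool with the real totals, the first number had a median of 318 and a highest value of 361, so read totals may account for it. The draws held counting error alone, without the further spread seen between the real libraries, so they cannot settle this. They also missed the second number, with a median of 29 and a lowest value of 17, above the 7 observed, a gap that was not tested further.

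Sham replicates 1 and 3 had few circRNAs with exactly 1 read. Among circRNAs with 2 to 4 reads expected from the SCI libraries, 10.02% and 5.31% had 1 read, against 14.3% to 18.0% in the SCI libraries and 18.0% in sham replicate 2 (Wilson 95% interval 14.7 to 21.8). That value goes against sham surgery as such, but it is a single library, so this stays open. At 8 to 20 expected reads the squared deviation over the expectation was 6.76 in sham replicate 3 (95% interval 4.23 to 11.02), 5.38 in sham replicate 1 (3.49 to 8.75) and 3.25 in sham replicate 2, against a highest upper bound of 4.29 in the SCI libraries. The expectation for an SCI library came from the other SCI libraries, and that for a sham library from the other group. Differences between the groups therefore raise the sham values, and the SCI bound is not a like measure. Reads counted in clumps, as duplicates are, and a higher read minimum in those libraries cannot be told apart, because both of these intervals reach below that SCI bound. Neither can be told apart from differences between the groups.

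CircRNAs with a circBase identifier took a lower share of reads in all 3 sham libraries, by 3.70 percentage points between the nearest libraries. The lower totals in sham, together with the table's 2-read minimum, were examined by thinning. At equal totals with 2 reads asked for in the library itself, the gap was 7.57 points, beyond the larger SD of 1.07. A gap under that rule thus did not need unequal totals. The table asks for 2 reads in any library, so its own minimum was not tested. The stricter rule drops single-read circRNAs, of which sham replicates 1 and 3 had few. Mean shares went from 67.0% to 70.6% in SCI and from 61.1% to 61.0% in sham. The widening therefore cannot be set against lower totals with the table's minimum, which stay open. Clumped reads cannot be told apart from other causes, since sham replicate 2, with the lowest such deviation in sham, also had a low share (62.7%) but is a single library. Nor can a few abundant junctions without an identifier: leaving out circRNAs with a mean of 20 or more reads narrowed the gap to 1.30 points, within the sham SD of 2.83. Injury itself stays open and untested, and it may be confounded with any difference in library preparation between groups.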
